A study of Homo sapiens with 70 samples.

How the data were processed

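The series holds 70 samples of H1 human embryonic stem cells: 52 RNA-seq libraries in 3 tables and 18 ChIP-seq libraries, 11 with a peak list and 7 inputs without files. RNA-seq libraries were made from polyadenylated RNA with a stranded mRNA kit and read on a HiSeq 4000, and ChIP-seq libraries on a HiSeq 2500, per the labels' protocols. The submitters' processing notes name FastQC 0.11.5, STAR 2.5.1, HOMER 4.8, edgeR 3.16.1 and the human genome build hg19, without the role or order of each. Groups were taken from the labels (genotype, treatment, time and table). All columns of values were mapped to a sample.

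The 24 h and 72 h table holds whole-number counts per gene for 34 libraries, deposited without scaling as far as the values show, with totals of 9.022 to 27.356 M. The day 25 table holds expected counts for 6 libraries: 32.83% of the deposited values are not whole and end in 0.5, and the counting tool is not stated; totals are 40.449 to 55.228 M. The 30 h table holds scores for 12 libraries, here counts that the authors had scaled to nearly the same total and rounded, as the deposited values show. Its totals differ by 0.0292%, and the steps between low values put 1 read at 0.614 to 1.833. The peak lists hold the score that the authors' peak caller gave each peak, as deposited, used only to rank peaks within a list. A symbol listed more than once was kept once (1 row dropped in each of the tables of 12 and 34 libraries).

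Counts were analysed with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1): TMM factors, the default expression filter and robust quasi-likelihood tests on all groups of a table, with 1 mean per group. Expected counts were rounded first. The planned test for the 30 h table was edgeR, but scaled scores do not carry count noise, so log2(score + 1) was fitted with limma-trend, for genes of at least 10 in at least 2 libraries. Differences between responses were tested as interactions. Of the rows, 17625 genes (24 h and 72 h), 16458 (day 25) and 16329 (30 h) were tested in 28 contrasts, with p adjusted by Benjamini-Hochberg within each contrast and a threshold of 0.05. Levels are CPM, averaged within groups. They are counts per M of a library's effective total, which is its total over the tested genes times its TMM factor. In the 30 h table they are per M of the plain total. Where a group had 0 counts, the ratio is a lower bound against a floor of 3 counts over the group (0.0789 CPM in untreated YAP-KO, on plain totals), and no fold is given in the 30 h table.

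Before the data were examined, 26 gene lists (signalling targets, germ layers, cell states and cardiac and other cell types) and the rule for named genes were fixed. Some lists share members, so their results are not independent. The primitive streak list shares FOXA2, CER1, GSC, EOMES and LHX1 with definitive endoderm. It also shares T, SP5, CDX1 and CDX2 with Wnt/β-catenin targets, and MIXL1, EOMES, NODAL and WNT3, among others, with Activin/Nodal targets. Lists were tested with camera at a preset correlation of 0.01 where at least 3 members were measured, adjusted over the lists of a contrast, and again with an estimated correlation. The numbers of members past the threshold are given over all genes and adjusted over the list alone. The rule names 16 genes chosen from the design, the 5 largest rises and 5 largest falls of each contrast among called genes of sufficient level, and up to 4 members with the largest called changes of each list discussed; the text leaves out some of them.

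Peaks of 2 lists were shared when they overlapped by at least 1 bp, with exact binomial 95% intervals, which cover counting error only. Each share was set beside 1000 random shifts of 10 to 100 kb. A peak was assigned to the gene named in the deposited list. Genes with peaks were compared with changed genes by Fisher's exact test, two-sided (Python 3.11.15, numpy 2.4.6, scipy 1.17.1; figures with matplotlib 3.10.9). Gene lengths came from the length column of a deposited count table. They were matched by symbol for 98.8% of the genes used and served only for length trends.

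Alternatives were size factors by RLE in place of TMM, no filter, DESeq2 1.42.0, the replicate number as a block, a fit to only the groups compared, each library left out, a pseudocount of 5 and a median-ratio rescaling for the 30 h table, and stricter, wider or narrower peak definitions. A library left out leaves a lone sample that is assumed to vary like the other groups.

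The fits were tested on simulated data drawn from the tables' means and library sizes, with 200 genes of over 50 counts on average changed. The spread of each gene came from the fit of the 24 h and 72 h table, also for the 30 h simulations, and from the day 25 fit for day 25. The 30 h values therefore do not measure the spread of the 30 h table. No library that stands apart and no trend with gene length was simulated. For untreated YAP-KO against WT (24 h and 72 h table, 17726 genes) 10.4% of 1.5-fold, 70.1% of 2-fold and 98.5% of 4-fold changes were recovered. For the Activin interaction at 24 h (17702 genes) these were 1.5%, 22.4% and 90.9%, for untreated YAP-KO against WT at 30 h (16417 genes) 3%, 50.7% and 100%, for the A50 interaction (16072 genes) 0%, 11.9% and 87.9%, and for day 25 (16424 genes) 26.9%, 77.6% and 95.5%. False calls made up 4%, 2.6%, 8.1%, 7% and 9.5% of the calls.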

Results

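RNA-seq of polyadenylated RNA and ChIP-seq, the sequencing of DNA recovered with an antibody to a chromatin-bound protein, were deposited for H1 human embryonic stem cells, an established pluripotent line kept in TeSR medium. The lines, made with CRISPR/Cas9 per the labels, were wild type (WT), a knockout of YAP, the Hippo-pathway cofactor of TEAD transcription factors (YAP-KO), and a knockout of YAP and of β-catenin, the Wnt-pathway cofactor (double knockout). The 52 RNA-seq libraries came in 3 tables. The 30 h table held 12 libraries, 2 each of WT and YAP-KO, untreated or treated for 30 h with A50 (Activin in the labels) or XV50 (XV in the labels, not explained further). The 24 h and 72 h table held 34 libraries in 17 groups of 2. WT and YAP-KO were untreated or given Activin, ChIR (as labelled) or both (Act+ChIR), and collected at 24 h, or at 72 h after a medium change at 24 h. The double knockout was untreated or given Activin or ChIR for 24 h. The day 25 table held 3 WT libraries (GSK3 inhibitor for 24 h, then Wnt inhibitor for 48 h) and 3 YAP-KO libraries (Activin for 24 h). ChIP-seq gave 11 peak lists, 1 library each with no replicate, and 7 input libraries without files.

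Total counts per library were 9.022 to 27.356 M in the 24 h and 72 h table and 40.449 to 55.228 M at day 25. In the 30 h table, which the authors had scaled, totals were 8.703 to 8.705 M, and the smallest steps between values placed the reads behind them at 4.75 to 14.18 M. Levels are CPM, counts per M of a library's effective total, which is its total over the tested genes times its TMM factor (the plain total in the 30 h table). Changes are log2 fold changes ± SE with adjusted p from edgeR, or from limma for the 30 h table. Groups have n = 2 (n = 3 at day 25), so each p measures only the spread between these libraries, and nothing in the labels says that replicates came from separate cultures. A library labelled WT Act+ChIR 24 h replicate 2 stood apart. Its correlation with its partner across genes was 0.882, against at least 0.979 within every other pair and up to 0.907 with libraries of other groups, and the difference between them followed gene length (Spearman rho across 10933 genes -0.735). It enters the shared spread of the 34-library table, so the number of genes called in each contrast of that table is also given without it.

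The targeted genes came first. YAP1 was lower in YAP-KO than in untreated WT, at 21.9 against 120 CPM (-2.45 ± 0.36, adjusted p 1.8e-05), in the 30 h table (-1.79 ± 0.14, adjusted p 2.4e-12) and at day 25 (43.3 against 254 CPM, -2.55 ± 0.17, adjusted p 1.12e-05). Over single libraries of the 24 h and 72 h table, YAP1 lay at 13.1 to 47 CPM in the 20 YAP-KO and double-knockout libraries and at 104 to 128 CPM in 13 of the 14 WT libraries. The remaining WT library, the one labelled Act+ChIR 24 h replicate 2, was at 30.4 CPM. In the 30 h table YAP1 was at 39.3 to 57.1 in the 6 YAP-KO libraries and at 140 to 243 in the 6 WT libraries, and at day 25 at 40.7 to 45.2 against 195 to 311 CPM. CTNNB1, which codes for β-catenin, was at 86.2 to 103 CPM in the 6 double-knockout libraries and at 257 to 580 CPM in the other 28 (double knockout against YAP-KO, untreated, -2.05 ± 0.16, adjusted p 1.24e-08). It did not pass in YAP-KO against WT (410 against 365 CPM, 0.17 ± 0.16, adjusted p 0.513). Both genes kept part of their RNA in the knockouts.

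What the loss of YAP changes in undifferentiated cells is addressed by untreated YAP-KO against untreated WT. Of 17625 genes tested in the 24 h and 72 h table, 3438 passed adjusted p 0.05, 1846 higher and 1592 lower. Leaving out 1 untreated library gave 2031 (WT replicate 1), 1946 (WT replicate 2) or 1794 (YAP-KO replicate 2), and 5090 passed without the library labelled WT Act+ChIR 24 h replicate 2. The 30 h table called 1604 of 16329 genes (579 higher, 1025 lower). Across 15675 genes measured in both tables the changes correlated with r = 0.550 and rho = 0.349 (genes are not independent replicates), and r fell to 0.304 when low-count genes were kept. Of 855 genes called in both, 839 moved the same way (98.1%). These were 247 higher and 592 lower, where independent lists would share 59.4 and 99.5.

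Of 24 measured YAP/TEAD target genes, 12 were lower and 1 higher in untreated YAP-KO (15 and 1 adjusted over the list alone; camera adjusted p 2.98e-14). At 30 h, 14 were lower and 1 higher, over all genes and over the list alone (camera adjusted p 4.01e-10; adjusted p = 0.079 with an estimated correlation). CTGF fell from 96.7 to 7.09 CPM (-3.77 ± 0.20, adjusted p 1.32e-12) and by 4.52 on the log2 scale in the 30 h table. CYR61 changed by -4.50 ± 0.27 and -4.05 ± 0.26 in the 2 tables, and AMOTL2 was at 2.57 against 115 CPM (-5.48 ± 0.36). ANKRD1 had 0 counts in YAP-KO and 0.69 CPM in WT, so it was at least 8.74-fold lower, counting 3 reads over the group as the floor. Changes in untreated cells ran weakly with gene length (rho -0.223 across 17396 genes), a trend that list tests do not remove and that reached -0.704 between the replicates of untreated YAP-KO.

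Among pluripotency genes 5 were higher and 6 lower of 22 (6 and 6 adjusted over the list alone; camera adjusted p 0.823). POU5F1 was higher (6210 against 3870 CPM, 0.68 ± 0.18, adjusted p 0.00816) and SOX2 lower (192 against 311 CPM, -0.70 ± 0.20, adjusted p 0.0156). POU5F1 no longer passed without replicate 2 of WT (0.63) or YAP-KO (0.52), nor SOX2 without WT replicate 2 (-0.61) or YAP-KO replicate 1 or 2 (-0.68 or -0.72). NODAL was higher in both tables (125 against 34 CPM, 1.88 ± 0.23, and 2.60 ± 0.13 at 30 h). LEFTY1 was higher at 30 h only (1.69 ± 0.21, against 0.27 ± 0.32, adjusted p 0.62; the difference between tables was not tested). The Activin/Nodal target list had 13 of 21 members higher and 3 lower in the 30 h table (the same over the list alone; camera adjusted p 1.36e-05; adjusted p = 0.222 with an estimated correlation), and 6 and 3 in the other table (camera adjusted p 0.259). Primitive streak genes had 6 higher and 1 lower of 23 (7 and 1 over the list alone; camera adjusted p 0.0136; adjusted p = 0.151 with an estimated correlation), MIXL1 among them (1.73 ± 0.32, adjusted p 0.000343). WNT3 was at 7.55 against 4.97 CPM (0.61 ± 0.26, adjusted p 0.108; adjusted p 0.0489 without the library labelled WT Act+ChIR 24 h replicate 2, and past the threshold in a fit to only the groups compared) and passed in the 30 h table (1.03 ± 0.16, adjusted p 7.69e-06). For 2 other lists the tables were not compared by a test. The p53 list was higher in the 24 h and 72 h table (6 and 0 of 18, the same over the list alone; camera adjusted p 0.0258) and lower in the 30 h table (1 and 5; 2 and 9 over the list alone; camera adjusted p 0.005), neither with an estimated correlation (adjusted p = 0.245 and 0.225). Glycolysis genes had 9 higher and 1 lower of 20 (11 and 2 over the list alone), against 1 and 4 of 19 (1 and 5; camera adjusted p 0.0154 and 0.0475; adjusted p = 0.343 and 0.671 with an estimated correlation).

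Among the largest changes, TEK of the endothelial list (0.878 against 63 CPM, -6.14 ± 0.39), TNNT2 of the cardiomyocyte list (-5.63 ± 0.47) and LINC00458 (7.05 against 333 CPM, -5.56 ± 0.23) were lower, and were also among the 5 largest decreases of the 30 h table. ZNF558 had 0 counts in YAP-KO against 15.7 CPM in WT, at least 198-fold lower. ZNF662 (5.54 ± 0.41) and RBM46 (4.64 ± 0.36; 2.34 ± 0.18 at 30 h) were higher.

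Whether YAP limits the response to Activin is addressed by Activin at 24 h in each line and by the difference of the responses, tested as an interaction. In WT 566 genes passed (342 higher, 224 lower), and leaving out any 1 of the 4 libraries gave 198 to 281. In YAP-KO 1725 passed (883 higher, 842 lower); leaving out YAP-KO untreated replicate 1 or 2 gave 753 or 914, and leaving out YAP-KO Activin replicate 1 or 2 gave 1149 or 747. Without the library labelled WT Act+ChIR 24 h replicate 2 the counts were 1258 and 3339. A fit to only the groups compared gave 2522 in WT. Primitive streak genes had 11 higher and 0 lower of 23 in WT (12 and 0 over the list alone; camera adjusted p 1.64e-48) and 18 and 0 in YAP-KO (20 and 0 over the list alone; camera adjusted p 2.13e-89). Activin/Nodal targets had 14 higher and 1 lower of 21 in WT (16 and 2 over the list alone) and 15 and 1 in YAP-KO (16 and 1). BMP/ID targets had 7 higher of 15 in WT and 8 in YAP-KO (9 over the list alone in each), and 0 lower in both. These list tests kept an adjusted p under 0.05 with an estimated correlation.

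Levels after Activin at 24 h are given for each line, and the treated lines were not tested against each other. T rose from 0.331 to 23.2 CPM in WT (6.14 ± 0.33) and from 0.632 to 148 CPM in YAP-KO (7.86 ± 0.31). EOMES rose from 0.366 to 30.9 CPM and from 0.292 to 132 CPM, and WNT3 from 4.97 to 37.1 CPM (2.90 ± 0.26) and from 7.55 to 72.6 CPM (3.26 ± 0.26). The responses of these 3 genes were not shown to differ between lines (interaction adjusted p 0.296, 0.414 and 0.913). MIXL1 rose from 1.2 to 16.1 CPM in WT and from 3.85 to 310 CPM in YAP-KO, and its interaction passed (2.54 ± 0.41, adjusted p 0.00164), though not without WT untreated replicate 1 (2.16). SOX2 was at 351 against 311 CPM in WT (0.17 ± 0.20) and fell from 192 to 50.7 CPM in YAP-KO (interaction -2.09 ± 0.29, adjusted p 0.000208). SOX17 had 0 counts in WT and 0.0306 CPM in YAP-KO, which was not detectable above the limit that a count of 0 allows (0.0747 CPM).

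**Figure D1:**
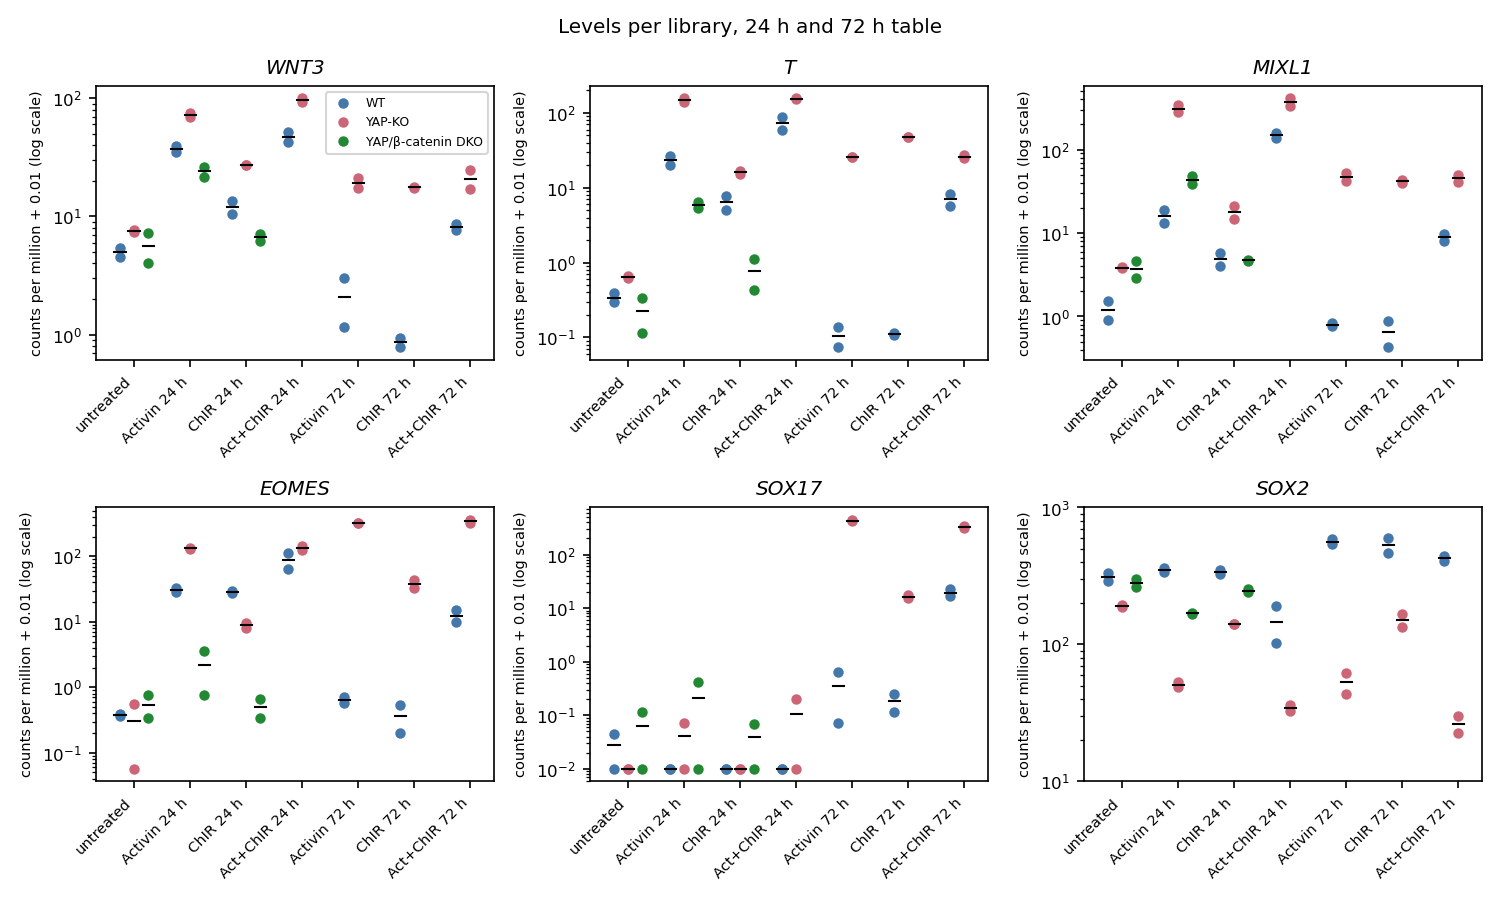
CPM plus 0.01 (log axis) of 6 genes in each library of the 24 h and 72 h table, by treatment, with WT in blue, YAP-KO in red and the double knockout in green; dots are libraries and black lines the means of the 2. After Activin for 24 h MIXL1 was at 16.1 CPM in WT, 310 CPM in YAP-KO and 43.6 CPM in the double knockout.

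The interaction at 24 h called 102 genes, 62 with a larger and 40 with a smaller response in YAP-KO; here and below larger and smaller give the sign of the difference in log2 change, which can also join a rise to a fall. Leaving out 1 library gave 55 to 63 for the WT untreated, YAP-KO untreated and WT Activin libraries and YAP-KO Activin replicate 1, DESeq2 gave 191, and 268 passed without the library labelled WT Act+ChIR 24 h replicate 2 (133 larger, 135 smaller). The primitive streak list had 4 members with a larger response and 0 with a smaller (9 and 0 over the list alone; camera adjusted p 1.8e-13), and the definitive endoderm list 3 and 0 of 20 (4 and 1 over the list alone; camera adjusted p 2.42e-08). The pluripotency list had 0 and 1 (camera adjusted p 0.0124). The trophoblast list had 0 and 0 of 12 past edgeR's threshold and passed as a set with a smaller response (0 and 2 over the list alone; camera adjusted p 0.00182). These 4 passed with an estimated correlation, and the Activin/Nodal targets (2 and 0) did not (adjusted p 0.000832; adjusted p = 0.17 with an estimated correlation). FOXA2 (4.41 ± 0.67), CER1 (4.16 ± 0.49; 188 CPM in YAP-KO after Activin) and FGF4 (4.91 ± 0.95; not past the threshold without replicate 2 of untreated WT, 4.39, or untreated YAP-KO, 4.8) had larger responses. FOXA2 and CER1 belong to both the streak and the definitive endoderm list, so the results of these lists rest partly on the same genes. CXCL14 went from 0.0299 to 8.37 CPM in YAP-KO and from 1.53 to 2.11 CPM in WT. NPTX1 (-3.21 ± 0.55) and SGK1 (-2.61 ± 0.35) had lower means after Activin in both lines, at 0.513 against 10.6 CPM and 4.16 against 33.3 CPM in YAP-KO, and 3.67 against 7.95 CPM and 9.38 against 12.2 CPM in WT.

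The 30 h table asks the same of A50. In WT 1345 genes passed, 63.3% of them higher (52.6% after a median-ratio rescaling); leaving out WT A50 replicate 2 gave 616 and WT untreated replicate 1 gave 704. In YAP-KO 6231 passed (3556 without YAP-KO A50 replicate 2). The interaction called 2190 genes, 1141 larger and 1049 smaller in YAP-KO (1455 without YAP-KO A50 replicate 2). EOMES reached 36.3 CPM in WT and 1160 CPM in YAP-KO (interaction 5.53 ± 0.23, adjusted p 1.11e-16), MIXL1 10.4 and 878 (5.45 ± 0.28) and SOX17 0.172 and 56.1 (7.14 ± 0.99). WNT3 reached 25.8 and 91.4 (0.80 ± 0.22, adjusted p 0.0117), and SOX2 368 and 17.6 (-3.91 ± 0.21). The WNT3 call ended without WT untreated replicate 1 (0.56), YAP-KO untreated replicate 2 (0.65) or YAP-KO A50 replicate 2 (0.77). LEFTY1 rose in WT from 37.4 to 101 and fell in YAP-KO from 121 to 36.8 (-3.18 ± 0.30). NODAL rose in both, from 15.8 to 172 in WT and from 95 to 390 in YAP-KO (-1.42 ± 0.19). In the interaction 15 of 20 cardiac mesoderm genes were higher and 0 lower (16 and 1 over the list alone; camera adjusted p 1.17e-12) and 13 of 18 definitive endoderm genes were higher and 1 lower (14 and 1; camera adjusted p 4.11e-12), and both passed with an estimated correlation. Streak genes (15 and 1 of 23; camera adjusted p 3.62e-12), Wnt/β-catenin targets (11 and 1 of 22; 2.03e-06) and pluripotency genes (3 and 11 of 22, 4 and 15 over the list alone; 0.000512) did not (adjusted p = 0.0595, 0.134 and 0.153 with an estimated correlation). Of 78 genes called in the interactions of both tables, all 78 moved the same way, 50 larger and 28 smaller in YAP-KO, where independent lists would share 4.4 and 2.7.

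At 72 h, 48 h after the medium change, Activin-treated WT differed from untreated WT in 5696 genes (2871 higher, 2825 lower; 3334 without WT untreated replicate 2, 3298 without WT Activin 72 h replicate 2, 9339 in a fit to only the groups compared) and YAP-KO in 8597 (4547 higher, 4050 lower). The interaction called 4410 (2357 larger, 2053 smaller in YAP-KO). Without the library labelled WT Act+ChIR 24 h replicate 2 these were 7523, 10223 and 6165 (2892 larger, 3273 smaller). Untreated libraries are labelled 0 h, so medium change and time in culture are part of each difference but cancel in the interaction if they act alike in both lines. WNT3 stayed above untreated in YAP-KO (19.2 against 7.55 CPM) and lay below it in WT (2.06 against 4.97 CPM, -1.26 ± 0.31, or -0.73 and no call without WT Activin 72 h replicate 2; interaction 2.61 ± 0.39, adjusted p 1.84e-05). T was at 25.6 CPM in YAP-KO and 0.0948 CPM in WT (interaction 7.02 ± 0.83), EOMES at 323 and 0.633 CPM (9.43 ± 1.20) and MIXL1 at 47 and 0.791 CPM (4.15 ± 0.49). SOX17 was at 430 CPM in YAP-KO, at least 5450-fold above untreated YAP-KO, which had 0 counts, and at 0.347 CPM in WT; its interaction did not pass (adjusted p 0.0515), but did by DESeq2, in a fit to only the groups compared, and without either WT Activin 72 h library or the library labelled WT Act+ChIR 24 h replicate 2. NANOG fell from 122 to 15.2 CPM in YAP-KO and from 87.4 to 52.7 CPM in WT (interaction -2.27 ± 0.25; the fall in WT lost its call without WT Activin 72 h replicate 2, -0.51). POU5F1 fell from 6210 to 1940 CPM in YAP-KO and was at 3140 against 3870 CPM in WT, past the threshold only in a fit to only the groups compared (-0.28; interaction -1.37 ± 0.25). SOX2 fell from 192 to 53 CPM in YAP-KO and rose from 311 to 563 CPM in WT (interaction -2.71 ± 0.29).

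In YAP-KO at 72 h, 19 of 20 definitive endoderm genes were higher and 1 lower, 20 of 23 streak genes higher and 1 lower, 17 of 21 cardiac mesoderm genes higher and 2 lower, and 14 of 15 BMP/ID targets higher, the same over the lists alone. Pluripotency genes had 4 higher and 17 lower, and the 20 cell cycle genes 2 and 18. In WT streak genes had 4 higher and 3 lower (camera adjusted p 0.81) and Activin/Nodal targets 5 and 11 of 21 (camera adjusted p 0.0453; adjusted p = 0.551 with an estimated correlation). Immediate early genes were higher in WT (12 and 5 of 20; camera adjusted p 7.33e-07; adjusted p = 0.113 with an estimated correlation), with EGR1 at 240 against 4.37 CPM. The interaction passed, also with an estimated correlation, for definitive endoderm (16 larger, 0 smaller in YAP-KO; 19 and 0 over the list alone; camera adjusted p 7.9e-30), streak (10 and 0; 12 and 0 over the list alone; 1.96e-10), cardiac mesoderm (12 and 1; 14 and 1; 1.89e-07), pluripotency (1 and 13; 2 and 15; 4.99e-08) and cell cycle genes (1 and 16; 1 and 16; 2.81e-06).

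**Figure D2:**
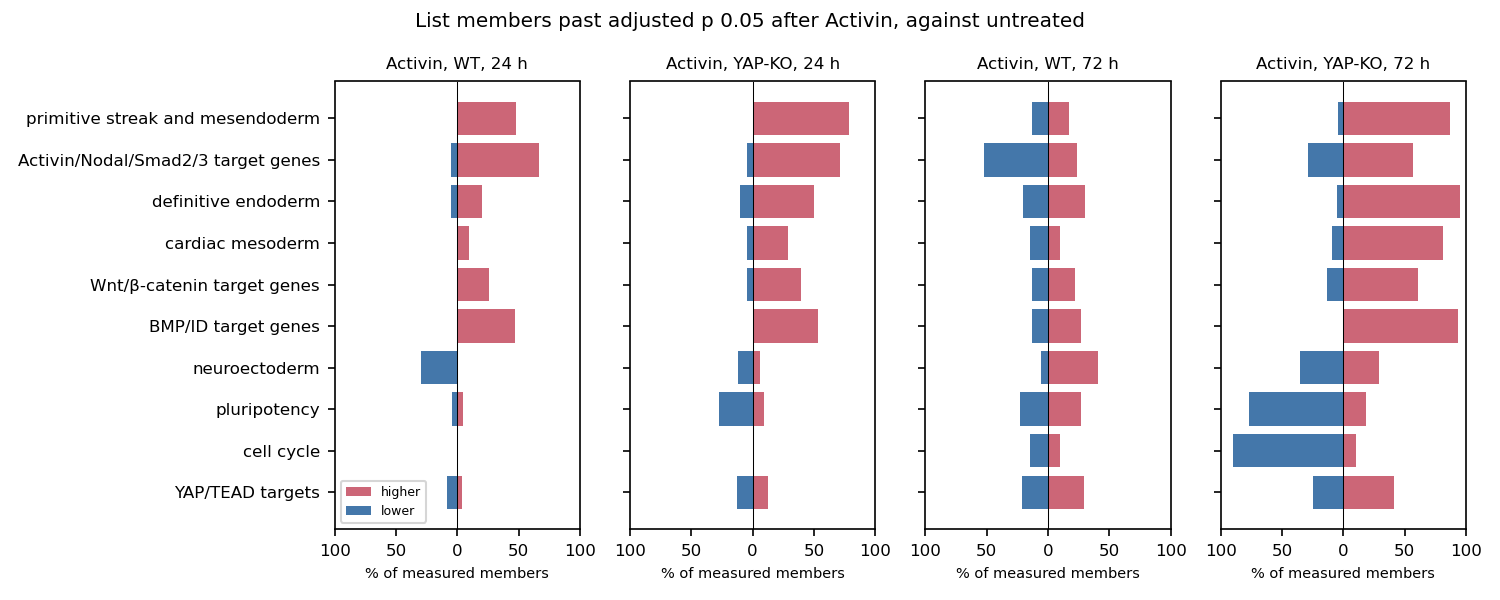
Share of the measured members of 10 gene lists, fixed before the data were examined, that were higher (red, right) or lower (blue, left) than untreated at adjusted p 0.05 after Activin (edgeR), for WT and YAP-KO at 24 h and 72 h. At 72 h 19 of 20 definitive endoderm genes were higher in YAP-KO and 6 in WT.

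ChIR asks about the Wnt side. At 24 h 639 genes passed in WT (346 higher, 293 lower; 197 to 269 when any 1 of the 4 libraries was left out, 4051 in a fit to only the groups compared) and 739 in YAP-KO (387 higher, 352 lower; 193 to 272 when any 1 of the 4 was left out, 1425 in a fit to only the groups compared). Without the library labelled WT Act+ChIR 24 h replicate 2 these were 1449 and 1817. Across genes the responses of WT and YAP-KO correlated with r = 0.366, and of 217 genes called in both, 212 moved the same way. Wnt/β-catenin targets had 11 higher and 1 lower of 23 in WT (14 and 2 over the list alone) and 7 and 1 in YAP-KO (8 and 1), and streak genes 10 and 1 in WT (14 and 1) and 10 and 0 in YAP-KO (11 and 0). SP5 rose in WT (7.74 ± 0.40) and in YAP-KO (6.22 ± 0.33), as did T (4.29 ± 0.35 and 4.66 ± 0.31) and WNT3 (1.28 ± 0.26 and 1.85 ± 0.25), whose call in WT ended without WT untreated replicate 2 (1.16) or WT ChIR replicate 1 (1.08). AXIN2 passed in WT (1.05 ± 0.27), though not without any 1 of the 4 libraries (0.95 to 1.14) or without a filter, and not in YAP-KO (0.04 ± 0.27). The difference for AXIN2 did not pass (-1 ± 0.38, interaction adjusted p 0.568), but did in a fit to only the groups compared (-0.99) and without the library labelled WT Act+ChIR 24 h replicate 2 (-1.02).

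The ChIR interaction at 24 h called 20 genes (16 larger, 4 smaller; 62 without the library labelled WT Act+ChIR 24 h replicate 2, 60 by DESeq2, 117 in a fit to only the groups compared). Leaving out a library left 2 (WT untreated replicate 1, YAP-KO untreated replicate 2 or WT ChIR replicate 2), 5 (either YAP-KO ChIR library), 8 (WT ChIR replicate 1) or 9 (YAP-KO untreated replicate 1). CTGF fell in WT (28.9 against 96.7 CPM) and rose in YAP-KO (13.4 against 7.09 CPM; interaction 2.66 ± 0.26, adjusted p 4.96e-06), and CYR61 fell in WT (26.6 against 90.4 CPM) with no call in YAP-KO (4.74 against 3.99 CPM; interaction 2.01 ± 0.36, adjusted p 0.0186). The rise of CTGF in YAP-KO (0.92 ± 0.19) lost its call without YAP-KO untreated replicate 1 or 2 (0.92 or 0.93) or YAP-KO ChIR replicate 1 (0.63), and the CYR61 interaction without any library of the 4 groups other than WT untreated replicate 2 (1.89 to 2.06). YAP/TEAD targets in WT had 0 higher and 5 lower of 24 (1 and 5 over the list alone; camera adjusted p 5.12e-07; adjusted p = 0.0656 with an estimated correlation). At 72 h the ChIR interaction called 1564 genes (1014 larger, 550 smaller; 1034 without WT untreated replicate 2, 981 without YAP-KO untreated replicate 2, 2676 without the library labelled WT Act+ChIR 24 h replicate 2). WNT3 was at 17.7 CPM in YAP-KO and 0.853 CPM in WT (3.76 ± 0.42), T at 47.8 and 0.1 CPM (7.85 ± 0.82) and FOXA2 at 80.7 and 0.15 CPM (7.92 ± 0.79; untreated 0.798 and 0.385 CPM). Streak genes had 11 larger and 0 smaller (14 and 0 over the list alone; camera adjusted p 4.92e-18) and Activin/Nodal targets 13 and 2 (16 and 3; 5.11e-25), both with an adjusted p under 0.05 with an estimated correlation.

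Act+ChIR at 24 h rests on the library that stood apart. In WT 5435 genes passed with it, 1761 without it and 9921 without its partner; leaving out WT untreated replicate 1 or 2 gave 3619 or 1844, and a fit to only the groups compared gave 0 (edgeR; 1503 at an unadjusted p under 0.05; DESeq2 on all groups gave 5866). Its changes ran with gene length (rho -0.497 across genes). Contrasts without the WT Act+ChIR 24 h group had -0.285 to 0.275. The Act+ChIR interaction at 24 h, which shares that group, had 0.409. In YAP-KO 2929 passed (1353 to 1721 when any 1 of the 4 libraries was left out, 4736 without the library labelled WT Act+ChIR 24 h replicate 2, 5075 in a fit to only the groups compared). The interaction called 1080 (426 larger, 654 smaller; 409 without the library, 7846 without its partner, 367 or 91 without WT untreated replicate 1 or 2, 446 or 106 without YAP-KO untreated replicate 1 or 2, 128 or 296 without YAP-KO Act+ChIR replicate 1 or 2, 2103 by DESeq2, and by edgeR 0 in a fit to only the groups compared, with 1575 at an unadjusted p under 0.05). MIXL1 reached 148 CPM in WT and 370 CPM in YAP-KO (interaction -0.40 ± 0.39, adjusted p 0.531) and T 73 and 154 CPM (0.13 ± 0.63, adjusted p 0.926). At 72 h the interaction called 3916 genes (2096 larger, 1820 smaller; 5723 without the library labelled WT Act+ChIR 24 h replicate 2, 2666 larger and 3057 smaller; 6231 in a fit to only the groups compared), with EOMES at 344 CPM in YAP-KO (5.24 ± 1.02) and no call for WNT3 (0.75 ± 0.36, adjusted p 0.146), except in a fit to only the groups compared (0.72).

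Whether Activin alone in YAP-KO acts like Activin with a Wnt signal in WT was asked by correlating responses at 24 h across 17625 genes. The response of YAP-KO to Activin correlated with that of WT to Activin with r = 0.442, to ChIR with r = 0.312 and to Act+ChIR with r = 0.481 (rho 0.448, 0.314 and 0.427). Which of Activin and Act+ChIR correlated more depended on the measure and on single libraries. For Act+ChIR r was 0.337 without WT Act+ChIR replicate 1. Without WT Act+ChIR replicate 2 it was 0.438, against 0.405 for Activin in the same fit (rho 0.405 against 0.433). The r for Act+ChIR fell below that for Activin without YAP-KO untreated replicate 1 (0.391 against 0.401) or YAP-KO Activin replicate 2 (0.372 against 0.392). There rho for Act+ChIR was 0.268 and 0.227. By rho Act+ChIR lay above Activin without YAP-KO Activin replicate 1 (0.534 against 0.438), YAP-KO untreated replicate 2 (0.509 against 0.427) or WT untreated replicate 2 (0.434 against 0.414), and without WT Activin replicate 1, which took Activin to 0.383. With low-count genes kept r was 0.201, 0.133 and 0.265 (rho 0.326, 0.225 and 0.318).

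The double knockout asks which part of the response needs β-catenin. Untreated, it differed from YAP-KO in 1140 genes (842 higher, 298 lower; 386 to 692 when any 1 of the 4 libraries was left out, 2201 without the library labelled WT Act+ChIR 24 h replicate 2). LINC00458 was at 507 against 7.05 CPM (6.17 ± 0.24) and NODAL at 67 against 125 CPM (-0.90 ± 0.22, adjusted p 0.0128; not past the threshold when any 1 of the 4 libraries was left out, -0.94 to -0.86). YAP/TEAD targets had 5 higher and 1 lower of 24 (the same over the list alone; camera adjusted p 0.043; adjusted p = 0.407 with an estimated correlation). Activin at 24 h changed 1035 genes in the double knockout (456 higher, 579 lower; 497 and 449 without replicate 2 of its untreated or Activin group, 2022 without the library labelled WT Act+ChIR 24 h replicate 2). Activin/Nodal targets had 16 higher and 1 lower of 21 (17 and 1 over the list alone; camera adjusted p 8.15e-50), streak genes 10 and 0 (11 and 1) and Wnt/β-catenin targets 3 and 2 of 23 (3 and 4; camera adjusted p 0.779).

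The Activin response of the double knockout differed from that of YAP-KO in 261 genes (72 larger, 189 smaller; 435 by DESeq2, 155 in a fit to only the groups compared, 589 without the library labelled WT Act+ChIR 24 h replicate 2). Leaving out a library gave 151 or 137 (YAP-KO untreated replicate 1 or 2), 149 or 168 (YAP-KO Activin), 139 (double-knockout untreated replicate 2) and 147 or 154 (double-knockout Activin). T reached 5.88 CPM (difference -3.13 ± 0.76, adjusted p 0.0344), MIXL1 43.6 CPM (-2.79 ± 0.36, adjusted p 4.58e-05), EOMES 2.19 CPM (-6.85 ± 1.02, adjusted p 0.000281) and SP5 0.506 CPM (-7.73 ± 0.60). WNT3 reached 24 CPM (-1.18 ± 0.35, adjusted p 0.112), LEFTY1 1270 CPM (1.01 ± 0.45, adjusted p 0.396) and SOX2 fell less (1.18 ± 0.29, adjusted p 0.0338). Leaving out any 1 of the 8 libraries ended the call of SOX2 (1.09 to 1.28), and any but double-knockout untreated replicate 1 that of T (-3.27 to -2.15); that library ended the call of EOMES (-6.15). WNT3 passed by DESeq2, without double-knockout untreated replicate 2 (-1.54) and without the library labelled WT Act+ChIR 24 h replicate 2 (-1.16). Of 23 streak genes 11 had a smaller response and 0 a larger (15 and 0 over the list alone; camera adjusted p 5e-34), of Wnt/β-catenin targets 5 and 0 (9 and 2; 3.98e-10), both also with an estimated correlation, and of Activin/Nodal targets 3 and 1 (6 and 2; 0.00638; adjusted p = 0.311 with an estimated correlation).

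ChIR at 24 h called 5 genes in the double knockout (1 higher, 4 lower), with 844 at an unadjusted p under 0.05, 37 by DESeq2, 23 in a fit to only the groups compared and 35 without the library labelled WT Act+ChIR 24 h replicate 2. Leaving out a library of the contrast left 0 or 1 (edgeR; 712 to 951 at an unadjusted p under 0.05 where 0 were left). GDF15 was higher (1.68 ± 0.26) and APELA, PDCD4, PBXIP1 and DEPTOR lower (DEPTOR, outside the rule for named genes, was chosen after its values were seen). PDCD4 did not pass without a filter, nor DEPTOR by DESeq2. T was at 0.767 against 0.216 CPM (adjusted p 0.849). The difference from YAP-KO called 14 genes (1 larger, 13 smaller; 52 by DESeq2, 49 in a fit to only the groups compared, 75 without the library labelled WT Act+ChIR 24 h replicate 2; 5 without double-knockout untreated replicate 1, 6 or 7 without YAP-KO untreated replicate 1 or 2, 8 without YAP-KO ChIR replicate 2, 7 or 9 without double-knockout ChIR replicate 1 or 2). SP5 responded less (-5.51 ± 0.54, adjusted p 5.29e-06). As a set the streak genes did too (1 of 23 smaller, 9 over the list alone; camera adjusted p 5.5e-24).

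XV50 at 30 h changed 4978 genes in WT (3023 without WT untreated replicate 2, 3184 without WT XV50 replicate 1) and 5419 in YAP-KO. The responses correlated across genes with r = 0.816, and of 3504 genes called in both, 3475 moved the same way. Streak genes had 22 of 23 higher in WT and 23 in YAP-KO, and Wnt/β-catenin targets 18 higher and 1 lower of 22, and 19 and 1 (camera adjusted p 5.83e-22, 4.31e-22, 1.09e-13 and 4.1e-13; adjusted p = 0.0544, 0.0536, 0.0548 and 0.0544 with an estimated correlation). AXIN2 rose by 3.15 ± 0.13 and 2.54 ± 0.13 and DKK1 by 9.98 ± 0.18 and 10.50 ± 0.18. The interaction called 477 genes (251 larger, 226 smaller; 268 without YAP-KO XV50 replicate 2), with AMOTL2 (4.40 ± 0.20) larger and NODAL (-2.62 ± 0.19) smaller in YAP-KO. T was not called (0.25 ± 0.62, adjusted p 0.967), except without WT untreated replicate 2 (1.04).

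Cardiac differentiation to day 25 is addressed by YAP-KO cultures given Activin against WT cultures given GSK3 and Wnt inhibitors, so genotype and protocol change together. Of 16458 genes 10503 passed (5349 higher, 5154 lower). All 16 measured fibroblast and extracellular matrix genes were higher (median 6.51, camera adjusted p 2.09e-34), DCN at 1130 against 0.872 CPM (10.34 ± 0.24) and COL3A1 at 19100 against 76.2 CPM. Of 28 cardiomyocyte genes 24 were lower and 1 higher (median -1.37, camera adjusted p 3.55e-09), MYL2 at 90 against 558 CPM (-2.63 ± 0.48), and MYH7 of the ventricular list was at 3370 against 13800 CPM (-2.03 ± 0.13). Liver and gut endoderm genes had 13 of 15 lower and 2 higher (median -5.57, camera adjusted p 9.1e-06), ALB at 0.496 against 479 CPM and AFP at 3.22 against 1870 CPM. Cell cycle genes had 17 of 20 lower and 0 higher (8.22e-05). Immediate early (14 higher, 4 lower of 20; 0.000519), smooth muscle (6 and 1 of 11; 0.000575), endothelial (8 and 0 of 14; 0.000916) and neural genes (4 and 0 of 8; 0.00472) were higher as sets. None of these 8 calls held with an estimated correlation (adjusted p = 0.21 to 0.632). CTGF (1.64 ± 0.14) and CYR61 (1.93 ± 0.14) were higher in YAP-KO, the opposite of the untreated cells.

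The other lists at day 25 did not pass by camera. Members higher and lower were 12 and 4 of 24 YAP/TEAD targets (camera adjusted p 0.0582), 5 and 2 of 12 pluripotency, 7 and 4 of 11 streak, 8 and 7 of 21 cardiac mesoderm, 3 and 10 of 17 definitive endoderm (0.074), 4 and 3 of 8 neuroectoderm, 3 and 4 of 10 trophoblast and 10 and 5 of 16 Wnt/β-catenin target genes. They were 2 and 3 of 10 Wnt ligands, 7 and 5 of 16 Activin/Nodal targets, 6 and 1 of 15 BMP/ID targets, 7 and 8 of 17 epithelial to mesenchymal transition, 7 and 5 of 18 p53, 3 and 6 of 20 glycolysis, 6 and 4 of 14 atrial, 3 and 4 of 10 ventricular, 4 and 2 of 7 epicardial and 2 and 4 of 7 skeletal muscle genes. Adjusted over the list alone the day 25 counts were the same except for cardiomyocyte (25 lower), Wnt/β-catenin target (6 lower) and epithelial to mesenchymal transition genes (8 higher). The last list joins epithelial and mesenchymal genes, so opposite changes cancel in its set test. Over all genes, its 8 lower members except CDH2 (-1.02) were epithelial genes such as CDH1 (-5.14) and EPCAM (-3.95). Its 7 higher members were mesenchymal genes such as SNAI2 (3.29) and MMP2 (4.66). These parts were not tested as sets. POU5F1 was at 4.5 against 0.0632 CPM, and T at 0.376 CPM against 0 counts, at least 17.9-fold higher.

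**Figure D3:**
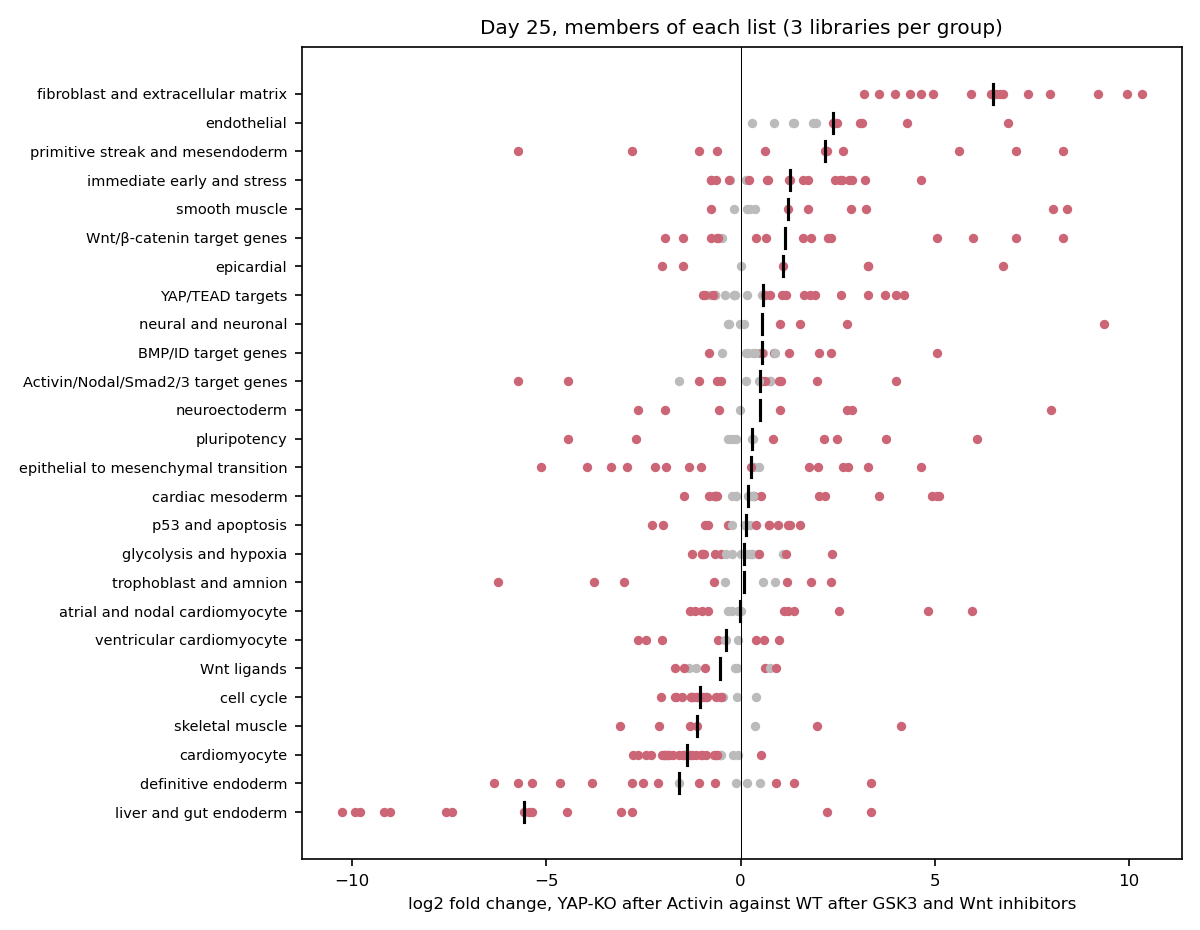
Log2 fold change at day 25 of each measured member of 26 gene lists, YAP-KO after Activin against WT after GSK3 and Wnt inhibitors (3 libraries each, edgeR); red dots passed adjusted p 0.05, grey did not, and black bars are list medians. The medians ran from -5.57 for liver and gut endoderm to 6.51 for fibroblast and extracellular matrix genes.

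YAP was mapped in untreated WT (2298 peaks), with YAP-KO as the antibody control (55 peaks), and TEAD4 in WT (7004 peaks). Peaks are the authors', on build hg19, and peak scores are used only within a list. Of the YAP peaks in WT 44.1% overlapped a TEAD4 peak (1013; 95% exact interval 42.0 to 46.1), against a mean of 0.2% after random shifts, and 0.2% overlapped a YAP-KO peak. The share with TEAD4 was 62.6% between the upper-scoring parts of both lists. The shifts do not keep peaks at sites of a like kind, so lists that favour the same kind of site can exceed them. The YAP-KO control list did so too, with 7.3% of its 55 peaks overlapping YAP peaks in WT, against a mean of 0.12% after shifts. After Activin for 15 h, β-catenin had 1963 peaks in WT and 1807 in YAP-KO, and 31.7% of the former overlapped the latter (29.6 to 33.8). Smad2/3, the Activin effectors, had 4342 and 11978, and 60.5% of the WT peaks overlapped a YAP-KO peak (59.0 to 62.0). β-Catenin peaks overlapped Smad2/3 peaks in 30.3% of cases in WT (28.2 to 32.3) and in 60.8% in YAP-KO (58.5 to 63.1). List lengths differed, with 1 library each, so a difference in peak number or overlap between the lines cannot be set against replicate error. Of the YAP peaks in WT 15.4% overlapped Smad2/3 and 13.6% β-catenin peaks of Activin-treated WT.

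**Figure D4:**
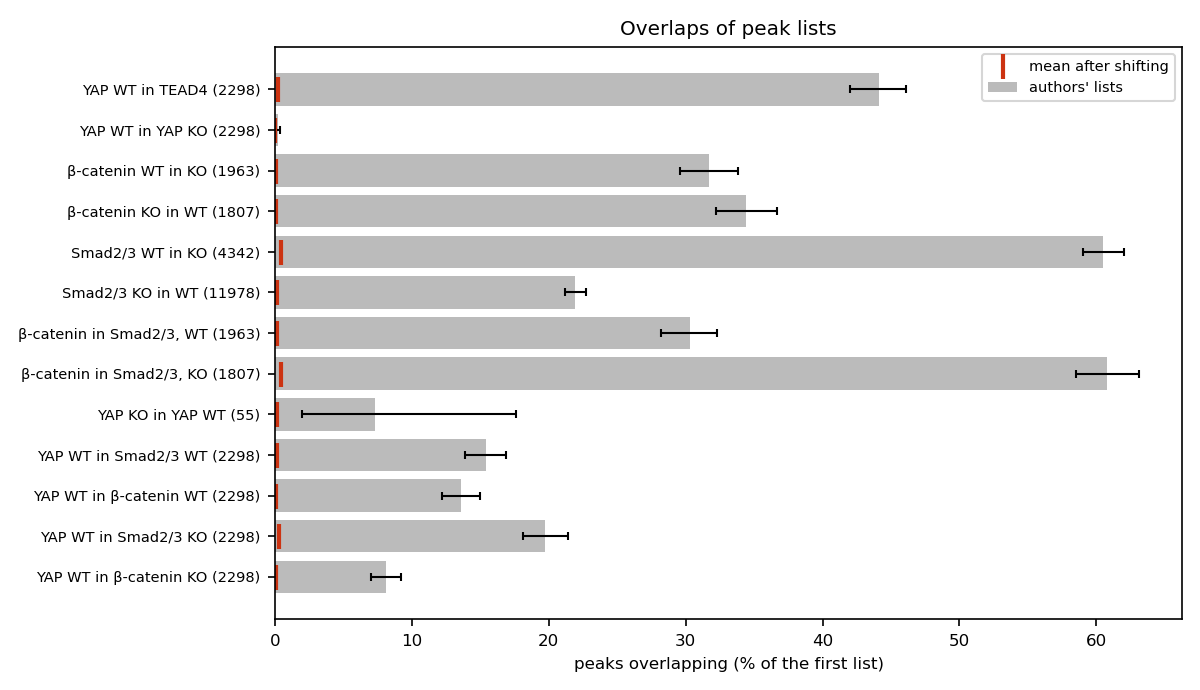
Percent of the peaks of a first list that overlap a second by at least 1 bp (bars, with 95% exact intervals from counting error), and the mean after 1000 random shifts of the first list (red marks); numbers in brackets are peaks of the first list. The highest mean after shifting was 0.43%.

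At WNT3 on chromosome 17 (hg19), the annotation in the peak lists placed 3 YAP peaks in WT. They were 44849739 to 44849959 in intron 2 of 4 (transcript NM_030753, 46277 bp inside the start of transcription), 44896581 to 44896801 at the promoter (-565 bp) and 44910538 to 44910758 in intergenic sequence (-14522 bp), with ranks 394, 1522 and 1755 of 2298 by score. No TEAD4 or YAP-KO peak was assigned to WNT3. The intron 2 site carried β-catenin peaks in WT (rank 26 of 1963) and YAP-KO (rank 68 of 1807) and Smad2/3 peaks in WT (rank 15 of 4342) and YAP-KO (rank 16 of 11978). A site from 44898979 to 44899423 (-3075 bp) carried Smad2/3 in both lines and β-catenin in the YAP-KO list only. At CTGF the YAP peak at 132272512 to 132272732 on chromosome 6 ranked 3 of 2298, with a TEAD4 peak of rank 50 of 7004 and a peak of rank 8 of 55 in the YAP-KO control. At NODAL a YAP peak upstream of the gene (-13803 bp, rank 51) shared its site with TEAD4, β-catenin and Smad2/3.

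**Figure D5:**
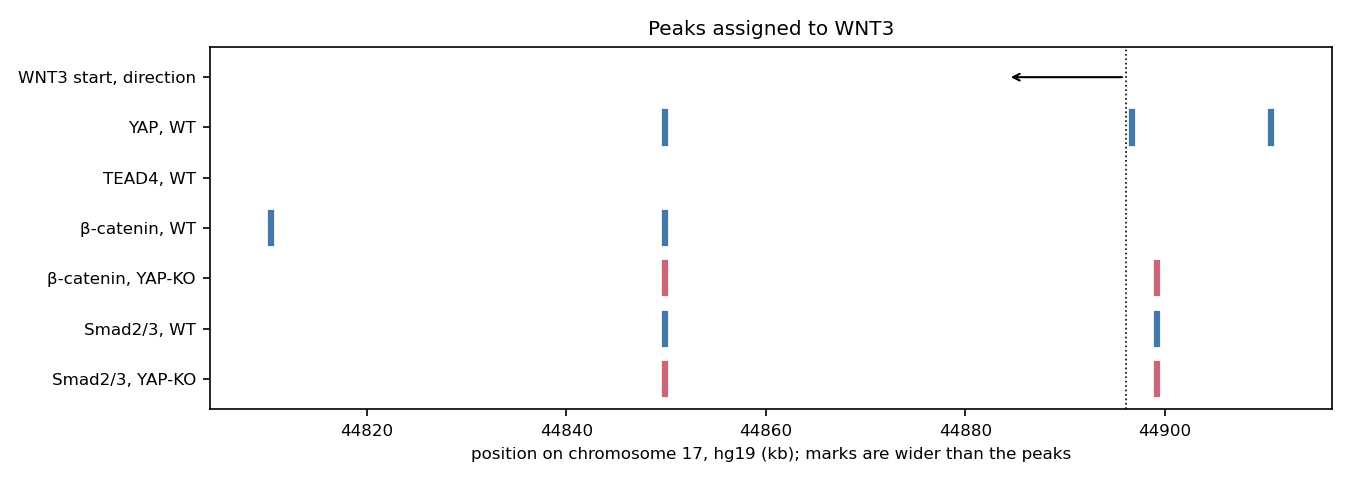
Peaks assigned to WNT3 on chromosome 17 (hg19, kb), with WT in blue and YAP-KO in red, marks wider than the peaks; the dotted line is the start of transcription at 44896126 and the arrow its direction. The intron 2 site held YAP, β-catenin and Smad2/3 peaks, and no TEAD4 peak was assigned to the gene.

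Whether bound genes changed was tested by Fisher's exact test, two-sided, over the genes tested in RNA-seq, with p adjusted over the 4 tests. A gene counted as bound when the lists name it as nearest to a peak, and genes were not matched for length or spacing. YAP peaks named 270 of 1592 genes lower in untreated YAP-KO (17%) against 7.6% of the other genes (odds ratio 2.5, adjusted p 8.82e-31), and 139 of 1846 genes higher in YAP-KO (7.5%) against 8.5% (odds ratio 0.88, adjusted p 0.156). Upper-scoring YAP peaks named 2.4% of the higher genes, against 4.0% of the other genes (odds ratio 0.6, unadjusted Fisher p 0.000537). With peaks within 10 kb of the start of transcription the shares were alike (odds ratio 0.98, unadjusted Fisher p 0.951). For the higher genes, the other genes include the lower genes, which were rich in YAP peaks (17%, or 10.6% with upper-scoring peaks). A depletion against unchanged genes was therefore not tested. YAP peaks named 14 of 24 YAP/TEAD targets (58.3%, against 8.4% of tested genes). β-Catenin peaks found only in YAP-KO named 10 of the 62 genes with a larger Activin response in YAP-KO (16.1%, against 3.9%; odds ratio 4.78, adjusted p 0.000178), and with the upper-scoring peaks 3 (odds ratio 3.29, p 0.0696). Smad2/3 peaks found only in YAP-KO named 38 of the 62 (61.3%, against 28.2%; odds ratio 4.04, adjusted p 1.73e-07; odds ratio 6.29 with the upper-scoring peaks and 2.96 with peaks within 10 kb of the start of transcription). Peaks shared by both lines or found only in WT were not tested in this way. A gene named by a peak found only in YAP-KO can also hold shared peaks, as CER1 does for Smad2/3. The β-catenin and Smad2/3 tests therefore do not show that the excess is particular to peaks found only in YAP-KO.

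RNA polymerase II phosphorylated at serine 7 of its C-terminal domain (Ser7P), used by the study as a mark of elongation, was mapped after Activin for 15 h in WT, in YAP-KO and in YAP-KO cells with a doxycycline-inducible Flag-YAP (PiggyYAP), without and with doxycycline. Of the 62 genes 41 had a Ser7P peak in WT (66.1%, 95% exact interval 53 to 77.7), 50 in YAP-KO (80.6%, 68.6 to 89.6), 50 in PiggyYAP without doxycycline and 48 with it (77.4%, 65.0 to 87.1). Of all tested genes 76.6% to 79.0% had a peak. For genes called larger without the library labelled WT Act+ChIR 24 h replicate 2, the shares were 76.7% in WT and 84.2% in YAP-KO. Of all genes tested there, 75.7% and 77.8% had a peak. In PiggyYAP the shares were 85.7% without doxycycline and 85.0% with it. The intervals cover counting error only, and with 1 library each a difference between these cultures was not tested. Regions assigned to WNT3 covered 18.8 kb in WT, 69.9 kb in YAP-KO, 69 kb in PiggyYAP without doxycycline and 31.7 kb with it. All Ser7P regions together covered 72.5, 87.5, 91.9 and 89.8 Mb. For MIXL1 the lengths were 3.8, 16.2, 14.7 and 7.5 kb, for EOMES 5.1, 17.7, 15.9 and 9.4 kb, and for T 0.5, 21.2, 22.3 and 14.9 kb, in the same order. Not all genes had this order of lengths, and length differences were not tested: NODAL at 18.9, 27.1, 27.7 and 27.1 kb, LEFTY1 at 3.9, 2.5, 1.8 and 2.4 kb, CER1 at 3.2, 2.5, 3.2 and 1.4 kb, CTGF at 38.6, 32.8, 42.6 and 35.1 kb, and SOX17 and FOXA2 had no region in any of the 4 lists.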

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

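Of the tests in this part, the gene length test, the comparison with libraries of other groups, the test of a lower share of cardiomyocytes and the protocol test were chosen after the results were seen.

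Responses that differed between cell lines were picked out by a test of the difference itself (edgeR, or limma at 30 h; n = 2 per group). Between YAP-KO and WT the genes past adjusted p 0.05 numbered 102 for Activin at 24 h, 4410 for Activin at 72 h, 20 for ChIR at 24 h, 1564 for ChIR at 72 h, 1080 for Act+ChIR at 24 h, 3916 for Act+ChIR at 72 h, 2190 for A50 and 477 for XV50. Between the double knockout and YAP-KO they numbered 261 for Activin and 14 for ChIR at 24 h. The report gives their direction, and the values when a library was left out. No group held 4 or more samples, so no sample was tested for its distance from the others of its group.

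The library labelled WT Act+ChIR 24 h replicate 2 had YAP1 at 30.4 CPM, where its partner had 119 CPM, and CTNNB1 at 257 against 432 CPM. A TMM factor of 0.725 scaled its levels up, where the factor of its partner was 0.993. Of the 33 other libraries 3 correlated with it more than its partner did (0.882), all from lines without YAP: replicate 2 of YAP-KO Activin 24 h (0.907), of double-knockout Activin 24 h (0.889) and of untreated YAP-KO (0.884). Their own pairs differed by gene length too (rho -0.697, -0.631 and -0.704). That the library came from a line without YAP is argued against: over genes apart between the untreated lines its median place from WT (0) to YAP-KO (1) was 0.3, with the 13 other WT libraries at -0.01 to 0.34 and the 20 libraries without YAP at 0.84 to 1.03. The bound set beforehand for a WT library, below 0.3, had not allowed for treated WT libraries lying at up to 0.34. A bias with gene length, as from RNA quality, is a candidate explanation that had the values it needs: the difference from the partner ran with length at rho -0.735 (other pairs -0.704 to 0.499), and genes among the 20% shortest and the 20% longest lay 1.8 apart on the log2 scale, against at most 0.63 in other pairs. Length alone leaves YAP1 open, since 2.6% of 1402 genes of like length fell further than its -1.93. Neither a wrong treatment label within WT nor a biological explanation was tested.

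Of 125 genes more than 4-fold apart between untreated YAP-KO and WT at 30 h and apart the same way in the other table, 14 (11.2%) lay nearer to WT in the double knockout, which also lacks YAP, and 13 of these differed from YAP-KO by edgeR. LINC00458 was at 333 CPM in WT, 7.05 CPM in YAP-KO and 507 CPM in the double knockout. For these 14 genes a difference between clones unrelated to YAP and an effect of β-catenin loss cannot be told apart, since the labels name no second YAP-KO clone and the share lay between the bounds of 5% and 20% set beforehand. A return of the YAP/TEAD targets as a set to near WT is argued against: their median place in the double knockout was 0.8, near YAP-KO (1). Single targets ran from 0.48 (NUAK2) to 1.04 (MYOF), with AJUBA at 0.54 and LATS2 at 0.61. More targets were called higher than lower in the double knockout against YAP-KO, so a partial return of some stays open. Whether the double knockout was made from the YAP-KO clone is not stated, so a clone effect common to both stays open for all 125 genes.

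At day 25 fibroblast and extracellular matrix genes were higher in YAP-KO (median 6.51) and cardiomyocyte genes lower (median -1.37). A lower share of cardiomyocytes with the other cell types kept in proportion would raise the markers of every other type, and is argued against by the liver and gut endoderm list, with a median of -5.57 (quartiles -9.11 and -3.78). Genotype and protocol cannot be told apart, since 0 libraries of either genotype received the other protocol. The real split of the 6 libraries called 10503 genes (edgeR) and the highest of the others 0 (277 at an unadjusted p under 0.05); 1 of the 10 splits reached the real count, and 10 splits are too few for a share under 0.05. A change in the cell types that rose stays open.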

How the results depend on the processing

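In this part, the pseudocount of 5, the resized peaks and the fits without the library labelled WT Act+ChIR 24 h replicate 2 were chosen after seeing the data; the other alternatives were fixed before. Where a value moved, the cause was not tested unless it is given. With a library left out, the lone sample of its group is assumed to vary like the other groups. DESeq2 was not run on the scaled 30 h table, nor was a smaller fit on the day 25 table, which holds only the 2 groups compared.

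Over the 28 contrasts, RLE size factors (21 results), no filter (28), the replicate block (28), the rescaling (7) and the pseudocount (7) moved no count of genes by over 1.5 times. DESeq2 moved 6 of 21, the fit to only the groups compared 12 of 27, a library left out 81 of 152, and leaving out the library labelled WT Act+ChIR 24 h replicate 2 moved 15 of 20. Of 1424 alternatives for genes named in the text, 1338 kept direction and side of the threshold, 71 lost the call, 15 gained it and none of these alternatives reversed a sign that was called.

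The replicate number was not taken to pair the libraries, since not every correlation between the deviations of libraries with the same number was over 0.1. In groups of 2 both numbers give the same correlation. Counted once, 10 of 15 were over 0.1 at 30 h (median 0.189, lowest -0.326), 61 of 136 in the 24 h and 72 h table (median 0.048) and 0 of 3 at day 25 (median -0.107, with 0 libraries nearest to their own number), so libraries of the 30 h table may share part of their deviations. With the replicate block untreated YAP-KO against WT called 3573 genes against 3438 in the 24 h and 72 h table. At 30 h all 7 counts rose, among them 1997 against 1604 (untreated YAP-KO against WT), 1987 against 1345 (A50 in WT) and 2729 against 2190 (A50 interaction). At day 25 the block gave 9693 against 10503. No named gene lost or gained its call.

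By DESeq2 the genes called were 191 against 102 for the Activin interaction at 24 h, 60 against 20 for ChIR, 2103 against 1080 for Act+ChIR, 435 against 261 (Activin) and 52 against 14 (ChIR) for the double knockout against YAP-KO, and 37 against 5 for ChIR in the double knockout. A fit to only the groups compared estimates the spread without the other groups. For Activin it gave 2522 against 566 (WT, 24 h), 9339 against 5696 (WT, 72 h) and 155 against 261 (double knockout against YAP-KO). For ChIR at 24 h it gave 4051 against 639 (WT), 1425 against 739 (YAP-KO), 117 against 20 (interaction), 23 against 5 (double knockout) and 49 against 14 (double knockout against YAP-KO). For Act+ChIR it gave 0 against 5435 (WT, 24 h; edgeR, 1503 at an unadjusted p under 0.05), 5075 against 2929 (YAP-KO, 24 h), 0 against 1080 (interaction, 24 h; 1575 unadjusted) and 6231 against 3916 (interaction, 72 h).

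With 1 library left out, including the library labelled WT Act+ChIR 24 h replicate 2, counts ranged as follows. Untreated: 1794 to 5090 (YAP-KO against WT) and 386 to 2201 (double knockout against YAP-KO). Activin: 198 to 1258 (WT, 24 h), 747 to 3339 (YAP-KO), 55 to 268 (interaction), 449 to 2022 (double knockout), 137 to 589 (double knockout against YAP-KO) and 3298 to 7523 (WT, 72 h). ChIR: 197 to 1449 (WT, 24 h), 193 to 1817 (YAP-KO), 2 to 62 (interaction), 0 to 35 (double knockout; edgeR, at least 712 unadjusted where 0), 5 to 75 (double knockout against YAP-KO) and 981 to 2676 (interaction, 72 h). Act+ChIR at 24 h: 1761 to 9921 (WT), 1353 to 4736 (YAP-KO) and 91 to 7846 (interaction). At 30 h: 616 to 1425 (A50, WT), 3556 to 5459 (A50, YAP-KO), 1455 to 2780 (A50 interaction), 3023 to 5017 (XV50, WT) and 268 to 449 (XV50 interaction). Fewer libraries lower the power of these fits, and counts without the library labelled WT Act+ChIR 24 h replicate 2 rose in 18 of 20 contrasts.

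The correlations r of the YAP-KO Activin response ranged from 0.376 to 0.416 (WT Activin), 0.265 to 0.299 (WT ChIR) and 0.337 to 0.49 (WT Act+ChIR) with a library left out, and were 0.201, 0.133 and 0.265 without a filter. The correlation of untreated changes between tables ranged from 0.477 to 0.552 (rho 0.237 to 0.41), with 94.5% to 99% of shared calls of the same sign, and was 0.304 (rho 0.236) without a filter, which adds genes of few counts. Of the list tests, 239 passed at the preset correlation and 105 with an estimated correlation.

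The upper-scoring parts of the lists shared more: 62.6% of YAP peaks with TEAD4, 42.6% of β-catenin peaks in WT with YAP-KO and 44.5% the other way, 77.6% of Smad2/3 peaks in WT with YAP-KO and 29.3% the other way, and 37.5% (WT) and 67.1% (YAP-KO) of β-catenin with Smad2/3 peaks. An overlap of at least 50% of the shorter peak gave 41.6% for YAP with TEAD4, 58.3% for Smad2/3 in WT with YAP-KO and 21.1% the other way. Peaks resized to 200 bp gave 57.6% and 20.9% for Smad2/3, and 58.1% for β-catenin with Smad2/3 in YAP-KO. Upper-scoring YAP peaks named fewer of the genes higher in YAP-KO than of all other genes (odds ratio 0.6, past the threshold). Those other genes include the lower genes, which were rich in YAP peaks. β-Catenin peaks found only in YAP-KO lost their call with upper-scoring peaks (odds ratio 3.29). Upper-scoring Ser7P peaks lay at fewer of the 62 genes in every list. The shares were 58.1% in WT, 66.1% in YAP-KO, and 71% and 67.7% in PiggyYAP without and with doxycycline. They also lay at fewer of all tested genes (67.4% to 70.6%). The directions of the other odds ratios held in these alternatives. With YAP peaks within 10 kb of the start of transcription, the odds ratio at genes higher in YAP-KO was 0.98.

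Depth limits folds from a group with 0 counts to lower bounds (a floor of 0.0789 CPM in untreated YAP-KO). At 9.022 to 27.356 M counts per library and n = 2, simulated changes of 2-fold, put only into genes of over 50 counts on average, were recovered for 70.1% of genes in untreated YAP-KO against WT and for 22.4% in the Activin interaction, so genes absent from the interaction lists are not shown to respond alike. The simulation varied neither depth nor gene level.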
